A study of Mus musculus with 11 samples.

How the data were processed

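RNA of 11 sorted tumour cell samples was extracted with a column kit and DNase treatment and made into Nextera XT libraries, per the labels' protocols. The authors deposited a table of estimated counts per gene, 1 column per library and all whole numbers. Per the submitters' processing notes kallisto 0.44.0 and DESeq2 (listed there as version 3.8) were used, with the genome build GRCm38, also named mm10. kallisto assigns reads to transcripts without aligning them to the genome; how transcripts were summed to genes and which annotation was used are not given in the sources used here. The table holds 17224 genes, 68 of them with 0 counts in every library, and no gene of the mitochondrial genome, so the list of mitochondrially encoded genes was not analysed here. Of its gene identifiers 17217 occur in GENCODE M21 and 16586 have the same coordinates there; gene coordinates are printed as deposited, and M21 was used for the exons of Atg12 and the strand of its neighbours.

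The authors also deposited a table of their own comparison of knockout and control. Per the file headers it gives a mean normalised signal per gene (baseMean), a log2 fold change with its standard error and a p-value, raw and adjusted. Of its 17235 rows 11 hold no values. Most of the deposited log2 fold changes lie very close to 0, so they appear shrunken; the method is not stated. Values from this table are named as the authors' wherever they are given.

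The estimated counts were used as whole numbers. The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, glmQLFit with robust = TRUE and glmQLFTest, two-sided, over all 6 control and 5 knockout libraries with no covariate, with Benjamini-Hochberg adjustment over the 13078 genes kept and a threshold of 0.05. Log2 fold changes are knockout minus control, and CPM are counts scaled to the library's total. The biological coefficient of variation was 0.358. Nothing in the labels gives a batch or date. Atg12 was also tested by an exact permutation of log2(CPM + 1) over all splits of the libraries.

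The 27 gene lists, the tests and the alternatives were fixed before the data were examined, except those named here as added. The 23 lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), with camera at an estimated correlation and with fry, each adjusted over the lists. An exact permutation of each list's mean log2 CPM (prior count 2) was added after seeing the data. The lists cover mammary cell states, autophagy and lysosomes, stress and inflammation, metabolism, the cell cycle, RNA quality and the other cells a lung sort could hold. Genes were named by a rule: Atg12; up to 10 genes per direction past the threshold with a mean of at least 5 CPM and at least 4 of 5 knockout libraries beyond the control median; where none passed, the 10 with the smallest unadjusted p, as values; and from each list up to 4 members past the threshold or, where no member passed, the 2 members with the smallest unadjusted p. For the erythroid and oxidative phosphorylation lists 1 of the 2 is not reported here. Other genes (the authors' calls, further members of the p53, NRF2, immediate-early and cargo receptor lists, Sftpc, Ptprc, Cd74, Dcn, Lum, Pdgfra, Pdk4, Angptl4, Cpt1a and the genes around Atg12) were chosen after their values were seen.

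The alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile factors, no low-count filter and a stricter one (5 CPM in 5 libraries), a replicate block, the macrophage list as covariate, a minimum log2 fold change of 1, and leaving out each library in turn. Leaving out knockout 1 and 4 together and using the lung epithelial list as covariate were added after seeing the data. Other calculations used Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1.

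The procedure was tested on simulated data, counts for the 13078 genes drawn from the libraries' means and totals with 200 changed genes and 3 shifted lists of 20 genes, whose members add to all calls but not to false calls. edgeR recovered 58% of the 100 genes changed 2-fold and 85% of the 100 changed 4-fold, with 6 false calls among 155; DESeq2 recovered 73% and 94% with 34 false calls among 221, and voom 53% and 83% with 7 among 148. In simulated lists of 20 genes, 3 of 3 shifted by 0.6 on the log2 scale were called, and 0 of 3 without a shift. The simulated genes were drawn independently of each other, whereas the real lists had estimated correlations of up to 0.847 (MHC class I). The simulation therefore does not show how often camera calls a correlated list without a shift. No simulated library was set apart from its group, as knockout 1 and 4 were in the data. The recovered shares and false calls above therefore hold only for libraries without such outliers. With 4563442 to 15203217 counts per library, a gene at 1 CPM rests on few counts in each.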

Results

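RNA was sequenced from mammary tumour cells that had grown as metastases in the mouse lung. The cells came from primary tumours driven by PyMT, the polyoma middle T oncogene, and carried GFP. After tail vein injection into 6-week-old C57BL/6 females they had 1 week to seed the lung. The autophagy gene Atg12 was then deleted in the tumour cells alone, and metastases grew for 3 more weeks. Atg12 is a ubiquitin-like protein whose conjugate with Atg5 is needed to attach LC3 to the growing autophagosome. Tumour cells were sorted from dissociated lungs as positive for GFP and MHC class I and negative for the leukocyte, endothelial and erythroid markers CD45, CD31 and Ter119. The 11 libraries comprised 6 from floxed controls with intact Atg12 and 5 from Atg12 knockouts. Each held 4563442 to 15203217 counts, with a mean of 8473706 ± 3385970 in controls (SD, n = 6) and 11727739 ± 2321348 in knockouts (SD, n = 5). No pair of libraries agreed within counting noise, the closest pair having a chi-square of 9.51 per degree of freedom. The labels number the replicates but do not say that each came from its own animal, so p-values measure the spread between these samples, which may be partly technical.

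The comparison asked what loss of autophagy changes in the transcripts of established metastatic tumour cells. Atg12 itself (ENSMUSG00000032905, chromosome 18, 46732417 to 46741579, GRCm38) had 52.1 ± 2.96 CPM (counts normalised to the library's total) in controls (SD, n = 6) and 30.4 ± 12.5 CPM in knockouts (SD, n = 5), so 58.3% of the control level remained. Controls lay between 47.1 and 55.7 CPM. The knockout libraries 1 to 5 held 9.94, 32.2, 33.3, 44.3 and 32.3 CPM, each below the lowest control. The exact permutation test, two-sided, gave p = 0.00216, the smallest value that the possible splits of the libraries allow. The fold change by edgeR was 0.59 (95% interval 0.387 to 0.903), with an unadjusted p of 0.0145 and an adjusted p of 0.579 over all genes by the quasi-likelihood test. Without knockout 1, the lowest library, the log2 fold change was -0.54, against -0.76 with all libraries. Which exon was deleted is not given in the sources used here. In the GENCODE M21 annotation exon 4, which carries the long 3' end, makes up 91.6% of the main transcript, so counts from outside the deleted part can remain. That exon reaches to 46730144, beyond the deposited end of the gene at 46732417, so its share in the deposited gene model is smaller. The counts per gene do not show what share of the sorted cells had lost Atg12. Knockout 4, with the most Atg12 of the knockouts, also had the highest means of the lung epithelial, endothelial and fibroblast lists described below. Knockout 1, with the least, also held 0 CPM of Atg14 and 0.113 of Atg10, against at least 21.06 and 10.08 elsewhere. Its Atg12 value may therefore not measure the deletion alone.

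**Figure D1:**
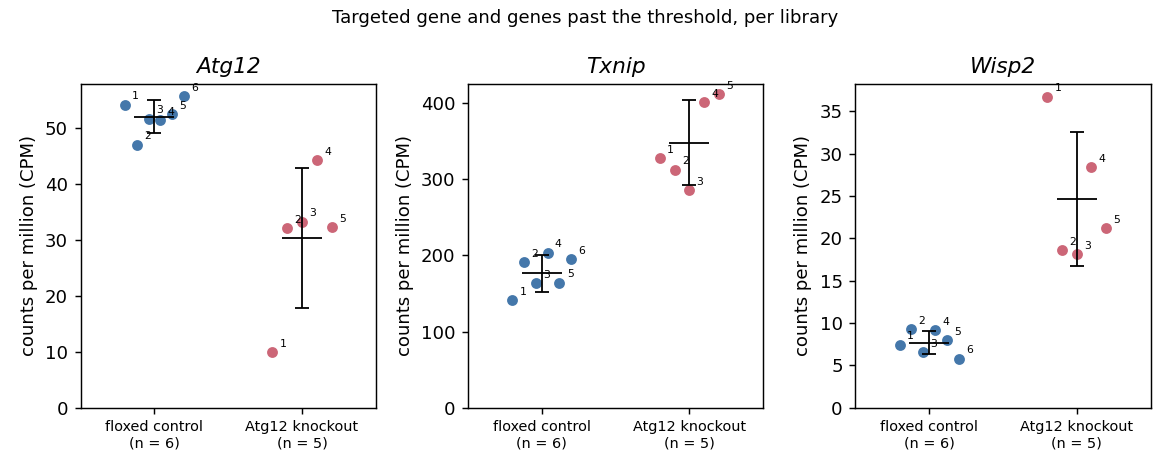
CPM (vertical axis, linear from 0) of Atg12, Txnip and Wisp2 in each library, with the replicate number beside each point and the mean ± SD of each group as black bars. All 5 knockout libraries lie below all 6 controls for Atg12, and above all 6 for Txnip (285.8 to 411.9 against 140.9 to 203.7 CPM) and Wisp2 (18.1 to 36.7 against 5.78 to 9.25 CPM).

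Among 13078 genes tested, Txnip and Wisp2 rose in the knockout cells and no gene fell past the threshold. Txnip, which encodes the thioredoxin-interacting protein, an arrestin-family inhibitor of glucose uptake (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883), rose 1.99-fold, from 176.4 ± 24.1 CPM in controls (SD, n = 6) to 347.9 ± 55.7 CPM in knockouts (SD, n = 5). Its log2 fold change was 0.99 ± 0.13 (SE). Wisp2, also called Ccn5, a secreted matricellular protein (ENSMUSG00000027656, chromosome 2, 163820861 to 163833146), rose 3.19-fold, from 7.69 ± 1.38 to 24.6 ± 7.92 CPM, with a log2 fold change of 1.67 ± 0.23 (SE). Both had an adjusted p of 0.0376 by edgeR. At an unadjusted p under 0.05 there were 747 genes higher and 298 lower by edgeR, where chance alone would give about 654 of the 13078 in both directions together. DESeq2 called 15 genes, all higher, and voom called 5 higher and 1 lower, the latter Atg12. The calls were not steady: leaving out any 1 of the 6 controls, or knockout 1, 4 or 5, left 0 genes past the threshold, and leaving out knockout 3 left Txnip alone, with 495 to 1371 genes at an unadjusted p under 0.05 over these and the other reduced sets of libraries. With the replicate number as a block 0 genes passed (smallest adjusted p = 0.377 by edgeR), though whether the numbers pair the samples is not settled. Both calls also ended with the macrophage list as covariate (adjusted p = 0.0709 for each; log2 fold changes of 0.94 for Txnip and 1.53 for Wisp2) and with the lung epithelial list as covariate (adjusted p = 0.202 for each; 0.86 for Txnip and 1.68 for Wisp2).

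No gene was called lower by edgeR, and the 10 genes with the smallest unadjusted p on that side are given as values (adjusted p = 0.579 for each). Hk2, the hexokinase that starts glycolysis, was at 40.3 ± 6.41 CPM in controls and 24.7 ± 4.77 in knockouts, a log2 fold change of -0.70 ± 0.17 (SE). Hspa5, the main chaperone of the endoplasmic reticulum, was at 1497 ± 158.1 and 1122 ± 101 CPM, a log2 fold change of -0.41 ± 0.10. Dnajb1, a heat-shock co-chaperone, had a log2 fold change of -0.50 ± 0.14, and Nfkbiz, a nuclear regulator of NF-kB, one of -0.48 ± 0.13. Nbea, Epb41l4b, Tsr1, Zfp692, Irf2bp2 and Rassf1 lay between -0.73 and -0.43.

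The authors' deposited table holds 10 genes past an adjusted p of 0.05, all of them higher in the knockout. In the authors' deposited table the log2 fold changes of these were 1.60 for Wisp2, 0.95 for Txnip, 2.20 for Cdo1 (cysteine dioxygenase), 1.14 for Ypel3, 0.61 for Ephx1 (epoxide hydrolase), 0.52 for Gas6 (a ligand of the Axl receptor), 2.50 for Itga7 (an integrin subunit), 0.61 for Ddit4l, 0.76 for Fxyd6 and 1.71 for Gpx2 (a glutathione peroxidase). Both genes called by edgeR are among them. In the edgeR fit all 10 had the same direction, and each of the 5 knockout libraries lay above the control median for each. Both results rest on the same libraries, so this is no separate support. For Atg12 the authors' deposited table gives a log2 fold change of -0.03, which appears to be shrunken, with p = 0.00807 and an adjusted p of 0.27.

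Target genes of p53, the DNA damage and stress regulator, were higher as a list in the knockout cells. Of 22 tested targets, 19 had positive fold changes, with a median log2 of 0.28, and the mean expression of the list was 5.73 ± 0.069 log2 CPM in knockouts (SD, n = 5) against 5.47 ± 0.072 in controls (SD, n = 6). Its lowest knockout library, at 5.65, lay above its highest control, at 5.58. Cdkn1a, the cell cycle inhibitor p21, had a log2 fold change of 0.64 ± 0.17 (SE; 200.2 ± 52.8 against 308.7 ± 49.3 CPM), and Ei24, a protein of the endoplasmic reticulum, one of 0.62 ± 0.19. Plk2 and Btg2 went the other way, at -0.30 ± 0.15 and -0.33 ± 0.18. No single member passed over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05, all higher. The camera test gave an adjusted p of 4.12e-05 and 0.0169 with an estimated correlation, fry gave 0.00322, and the exact permutation test of the list means, added after seeing the data, gave p = 0.00216 (adjusted p = 0.0249). The lung epithelial marker list described below was also higher in the knockouts, by 0.73 log2 units in its mean. With that list's mean as a covariate the p53 list stayed higher by 0.23 ± 0.047 (SE).

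The list of genes controlled by NRF2, the regulator of antioxidant and glutathione genes, had a higher mean in the knockouts, carried by part of its members. It passed camera at the preset correlation and the exact permutation test, but not camera at an estimated correlation or fry. Adjusted over the list alone, 4 of 24 tested members passed, all higher, while none passed over all genes. They were Gsta3 and Gstm1, which are glutathione transferases, Gpx2, and Gclm, a subunit of the enzyme that starts glutathione synthesis, with log2 fold changes of 1.38 ± 0.33, 1.62 ± 0.46, 1.93 ± 0.47 and 0.51 ± 0.14 (SE). Gstm1 was far above the controls (37.0 to 65.9 CPM) only in knockout 1 and 4, at 186.4 and 309.4 CPM against 49.6 to 65.9 in the other knockouts, and without knockout 1 the log2 fold change of Gpx2 was 1.30. Other well-known targets gave no such values, with Nqo1 at -0.11 ± 0.30 (19.8 CPM in knockout 4, 61.5 to 90.4 in the other knockouts, 46.9 to 98.4 in controls), Hmox1 at -0.23 ± 0.26 and Txnrd1 at 0.0009 ± 0.10. The list median was therefore only 0.06, with 17 members positive and 7 negative. The mean over the list was 6.80 ± 0.12 log2 CPM in knockouts (SD, n = 5) and 6.53 ± 0.061 in controls (SD, n = 6), the lowest knockout at 6.64 and the highest control at 6.63. The camera test gave an adjusted p of 0.00424, but 0.358 with an estimated correlation, and fry gave 0.16. The exact permutation test gave p = 0.00216 (adjusted p = 0.0249). Glutathione transferases are families of similar genes, between which reads can be split wrongly. With the lung epithelial mean as a covariate the list stayed higher by 0.25 ± 0.067 (SE).

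Markers of basal and myoepithelial cells were higher as a list in the knockouts and luminal and milk genes were lower, with a wide spread between libraries. Of 28 basal markers 26 had positive fold changes, with a median log2 of 0.47, and none passed over all genes or adjusted over the list alone. Krt5 and Krt14, the keratins of the basal layer, had log2 fold changes of 0.71 ± 0.22 and 0.73 ± 0.23 (SE), Krt14 being at 715 ± 158.4 CPM in controls and 1175 ± 474 in knockouts. Of 26 luminal markers 20 had negative values, with a median of -0.24. Cldn7, a tight junction protein, was at -0.31 ± 0.11 and Esr1, the oestrogen receptor, at -0.69 ± 0.26. Of 18 milk and alveolar genes 15 were negative, with a median of -0.47, among them Wap, a whey protein, at -0.76 ± 0.30 and Xdh at -0.52 ± 0.23. No luminal or milk gene passed over all genes or adjusted over the list alone. By camera the adjusted p was 8.02e-09 for the basal, 0.00381 for the luminal and 5.01e-05 for the milk list, and for each of them 0.46 with an estimated correlation. The exact permutation tests of the list means gave p = 0.0823, 0.307 and 0.0498, which became 0.315, 0.541 and 0.286 after adjustment. These are textbook markers, but they were chosen in the knowledge that the study concerns such cells, so the direction is not independent evidence. Knockout 1 and 4 carried much of it: without both, the medians were 0.17, -0.03 and -0.09 and only the basal list passed the camera test (adjusted p = 0.0002). Without knockout 1 alone the luminal list did not pass either (adjusted p = 0.0913, median -0.10), and with voom neither the luminal (0.07, adjusted p = 0.889) nor the milk list (-0.16, adjusted p = 0.094) did. With the lung epithelial mean as a covariate the basal list mean differed by 0.173 ± 0.187 (SE), against 0.437 without it.

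**Figure D2:**
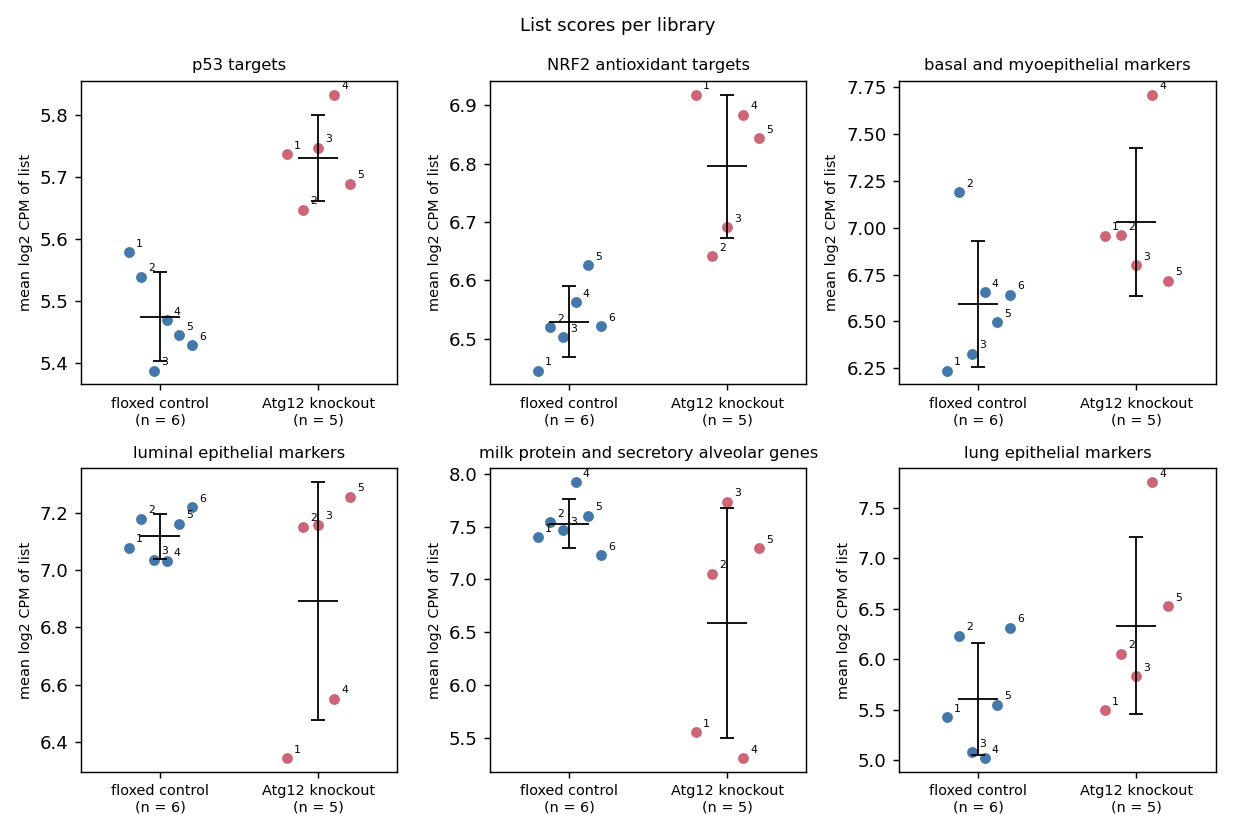
Mean log2 CPM of 6 gene lists (vertical axes, log2 scale, each with its own range) in each library, with the replicate number beside each point and the mean ± SD of each group as black bars. For the p53 and NRF2 target lists the 5 knockout libraries all lie above the 6 controls, while the basal, luminal, milk and lung epithelial lists overlap between groups and are widest in the knockouts.

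Knockout libraries 1 and 4 stood apart from the other 9. On the first component, which held 41.6% of the variance, they lay at 130 and 50.4, and the other libraries between -33.3 and -10.6. On the second, with 26.3%, they lay at 52.5 and -107. Their median Spearman correlation with the other libraries was 0.925 each, against at least 0.972 for the rest, and they had 13812 and 14854 genes with a count, against at least 15218.

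**Figure D3:**
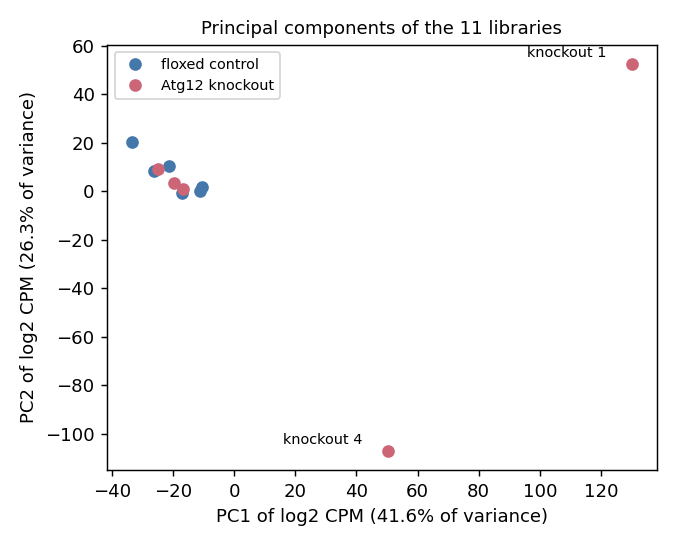
First and second principal component of log2 CPM over the 11 libraries (horizontal and vertical axes, with the percent of variance in the labels), controls in blue and knockouts in red. Knockout 1 (130, 52.5) and knockout 4 (50.4, -107) lie away from the other 9 libraries.

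Markers of other lung cells were present in all libraries in spite of the sort, and the lung epithelial, endothelial and fibroblast lists had their highest means in knockout 4. The lung epithelial list passed the camera test as higher in knockouts (16 genes, median log2 1.21, adjusted p = 0.000232, but 0.46 with an estimated correlation), and so did the fibroblast and pericyte list (12 genes, 1.20, 0.0016 and 0.46). Sftpc, the surfactant protein of alveolar type II cells, was at 2551 CPM in knockout 4 and at 191.1 to 1017 CPM elsewhere, and Lyz2, a lysozyme of macrophages and type II cells, was at 1051 CPM against 89.1 to 278.8. Without knockout 1 and 4 the lung epithelial median was 0.45 (adjusted p = 4.73e-06) and the fibroblast median -0.11 (adjusted p = 0.892); without knockout 4 alone the fibroblast list did not pass (adjusted p = 0.109), nor with the lung epithelial covariate (adjusted p = 0.26) or voom (median -0.02, adjusted p = 0.889). Napsa and Sftpd had log2 fold changes of 1.49 ± 0.50 and 1.73 ± 0.57 (SE), Mgp and Col1a2 of 1.44 ± 0.55 and 1.43 ± 0.55. Endothelial markers (10 genes, median log2 0.82, adjusted p = 0.0929; Ramp2 at 1.83 ± 0.84 and Cldn5 at 1.62 ± 0.83) did not pass with all libraries. They passed as higher without control 2 (adjusted p = 0.0281) or knockout 1 (0.0197), 2 (0.0159) or 5 (0.0312), while without knockout 4 their median was 0.05 (adjusted p = 0.896). Macrophage and monocyte markers (8 genes, adjusted p = 0.108; Lyz2 at 1.33 ± 0.54 and Lyz1 at 0.75 ± 0.52) passed only without knockout 2 (adjusted p = 0.0159), and this list holds MHC class II genes. Without knockout 4 the log2 fold changes of Napsa, Sftpd, Col1a2, Ramp2, Cldn5, Lyz2 and Lyz1 were 0.67, 0.74, 0.69, 0.56, 0.36, 0.44 and 0.12. Ptprc, which encodes CD45, was at most 3.59 CPM. Neutrophil, lymphocyte and erythroid lists had under 5 tested members and no list test. S100a8 and Ltf were at -0.98 ± 0.49 and -0.43 ± 0.36, Cd3d and Lck at -0.50 ± 0.43 and 0.26 ± 0.45 (Lck at -0.33 without knockout 1), and Alas2 at -0.62 ± 0.73. Ltf is also a milk gene.

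The list of mesenchymal transition genes was also higher by camera (22 genes, 18 of them positive, median log2 0.68, adjusted p = 0.000273, but 0.46 with an estimated correlation). Mmp14, a membrane-bound matrix protease, was at 0.63 ± 0.20 and Postn, the matrix protein periostin, at 0.59 ± 0.21 (SE). Without knockout 1 and 4 the median was 0.01 (adjusted p = 0.424), with voom 0.10 (adjusted p = 0.182) and with the lung epithelial covariate 0.36 (adjusted p = 0.0824). Several of these genes are also made by fibroblasts, whose markers exceeded the other 9 libraries for 9 of 12 genes in knockout 1 and 11 of 12 in knockout 4, with Mgp at 488 and 592 CPM against 73.8 to 141 elsewhere and Dcn, the matrix protein decorin, at 448 and 1330 against 57.9 to 241.

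Genes of protein folding stress, glycolysis and the immediate-early response were lower as lists, by small amounts. Of 27 unfolded protein and integrated stress response genes 20 were negative, with a median log2 of -0.19. Hspa5 alone passed when adjusted over the list alone, and Hsp90b1, a sister chaperone, was at -0.27 ± 0.10. Of 27 hypoxia and glycolysis genes 21 were negative, with a median of -0.15. Hk2 passed when adjusted over the list alone, while Slc16a3, a lactate exporter, was at 1.99 ± 0.67 with 0.838 ± 0.334 CPM in controls and 9.60, 0.92, 1.31, 3.68 and 1.18 CPM in knockouts 1 to 5; the log2 fold change of Slc16a3 was 1.12 without knockout 1 and 0.47 without knockout 1 and 4. Of 27 immediate-early genes, which respond to tissue dissociation, 20 were negative, with a median of -0.18, and Dnajb1, Ier2 and Ier3 passed when adjusted over the list alone. No member of these lists passed over all genes. The camera test gave adjusted p = 0.00288, 0.00575 and 0.00575, and 0.46 with an estimated correlation for each of the 3. The protein folding call ended with the lung epithelial covariate (adjusted p = 0.0699, median -0.07). The glycolysis call ended without knockout 1 (adjusted p = 0.0683, median -0.08), without knockout 1 and 4 (0.133, -0.02) and with voom (0.119, -0.02), and the immediate-early call without knockout 5 (adjusted p = 0.132, median -0.17).

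Autophagy and lysosome genes passed no list test. The list of 33 core autophagy genes, which leaves out Atg12, had a median log2 of -0.01 (adjusted p = 0.439 by camera), with Atg2a at -0.41 ± 0.21 (SE) and Ulk1 at 0.34 ± 0.20. Its mean was lowest in knockout 1, at 5.21 log2 CPM, against 5.56 to 5.71 in the other knockouts and 5.64 to 5.69 in controls. In that library Atg14 and Atg10 were at 0 and 0.113 CPM, against at least 21.06 and 10.08 elsewhere. The 15 cargo receptors, which bring material to the autophagosome, had a median of -0.01 (adjusted p = 0.894). Calcoco1 was at 0.33 ± 0.10, Tax1bp1 at 0.19 ± 0.11, and Nbr1, the receptor named in the study's title, at -0.23 ± 0.22. That value comes from knockout 1 and 4, with Nbr1 at 92.4 and 74.2 CPM, while knockouts 2, 3 and 5 were at 203.6, 170.5 and 170.8 and controls at 148.3 to 182.5. The 34 lysosome genes had a median of 0.03 (adjusted p = 0.461), with Npc2 at 0.33 ± 0.11 and Hexa at 0.94 ± 0.42 (0.23 without knockout 4). No member of these lists passed over all genes or adjusted over the list alone.

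The remaining lists gave no call that held under other tests. Ribosomal protein genes were higher by camera (36 of 36 positive, median 0.20, adjusted p = 2.63e-08, but 0.46 with an estimated correlation), with Rpl13 at 0.26 ± 0.11 and Rpl4 at 0.19 ± 0.09 (SE). Interferon-stimulated genes passed camera (35 genes, median 0.14, adjusted p = 0.0146, but 0.741 with an estimated correlation), with Irf7 at 0.34 ± 0.22 and Bst2 at 0.42 ± 0.34. That call ended with voom (adjusted p = 0.889) and without control 6 or knockout 1, 4 or 5, and without control 5 the median was -0.02 (adjusted p = 0.752). The median was -0.09 with the macrophage covariate (adjusted p = 0.402) and -0.14 without knockout 1 and 4 (adjusted p = 0.738). The macrophage list holds MHC class II genes, which followed the interferon list over the libraries (Pearson r = 0.956). Its covariate therefore cannot separate macrophages from an interferon state, either here or for the MHC class I list. MHC class I and antigen processing genes (median 0.17, adjusted p = 0.0799) did not pass with all libraries, but passed as higher without control 1 (median 0.32, adjusted p = 0.00109), control 3 (0.21, 0.00742), control 4 (0.29, 0.00363), knockout 2 (0.32, 0.00269) or knockout 3 (0.24, 0.0404) and with the lung epithelial covariate (0.19, 0.0387). Their median was 0.009 without control 5, -0.16 without knockout 1 and 4 (adjusted p = 0.424) and -0.09 with the macrophage covariate (adjusted p = 0.207). Their 2 members with the smallest p, Calr and Pdia3, went the other way, at -0.28 ± 0.10 and -0.28 ± 0.12. Cholesterol synthesis (median -0.06, adjusted p = 0.108; Lss at -0.50 ± 0.20 and Insig1 at -0.22 ± 0.12) passed as lower without control 2 (0.0271) or knockout 4 (0.00188), without knockout 1 and 4 (0.0381) and with either covariate. Cell cycle genes (-0.05, 0.172; Bub1 at 0.37 ± 0.18 and Mcm5 at -0.21 ± 0.15) passed as lower without control 2 (0.027) or 4 (0.011) or knockout 2 (0.0176) or 5 (0.0449). Nuclear-encoded oxidative phosphorylation genes (0.04, 0.343; Cox6c at 0.25 ± 0.15) passed as higher without control 5 (0.00697) or knockout 4 (0.00794), without knockout 1 and 4 (0.0183), with voom (0.00685) and with either covariate. NF-kB targets and inflammatory cytokines did not pass with all libraries (25 genes, adjusted p = 0.466), with a median of 0.08 and a mean of 0.14 although camera put the list on the lower side. Lif and Tnf were at -0.73 ± 0.21 and -0.67 ± 0.21. Without knockout 1 and 4 the median of this list was -0.36 (adjusted p = 2.56e-08), without knockout 4 alone -0.14 (adjusted p = 0.00794), with voom -0.28 (adjusted p = 8.93e-06) and with the macrophage covariate -0.16 (adjusted p = 0.00459).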

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

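The tests of lung cells and fibroblasts, of the genotype, of knockout 1 and 4, of the lung covariate, of dissociation stress and of other splits for unadjusted p were chosen after the result was seen; those of low-transcript loss and of other splits for called genes and lists were written before theirs.

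A library lying far from the rest of its own group was found 14 times in 174 groups of values, where chance gives about 1 in 20 groups. Of these, 7 fell in knockout 4, 4 in control 5, 2 in knockout 1 and 1 in control 1. In knockout 4 the basal list mean was 7.71 log2 CPM (nearest other knockout 6.96), the oxidative phosphorylation list mean 7.66 (7.88), Lyz2 1051 CPM (268), Lyz1 62.3 (19.9), Napsa 99.8 (25.2), Mmp14 192 (115) and Tnf 57.6 (124). In control 5 the oxidative phosphorylation list mean was 8.1 (7.87), the ribosomal protein list mean 10.1 (9.66), Tnf 134 CPM (191) and Irf7 202 (383). In knockout 1 Atg12 was 9.94 CPM (32.2) and the lysosome list mean 6.62 (6.91). Npc2 in control 1 was 296 CPM (281).

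Knockout 1 and 4 lay apart from the other 9 libraries on both leading components. Loss of weakly expressed transcripts alone is argued against, since over genes of at least 100 mean CPM their higher median correlation with the other 9 libraries was still 0.817, below the lowest of those 9 (0.869). Loss or noise that also reaches abundant transcripts would lower this correlation too, so it stays open. With every library thinned to 4563442 counts, knockout 1 and 4 had 13531 and 14445 genes with a count, the other 9 at least 14905. Lung cells left in the sort may account for part of the distance of knockout 4, whose scores for lung epithelial, endothelial and fibroblast markers all exceeded every other library (3 of 3), with Sftpc at 2551 CPM. In knockout 1 only the fibroblast score (1 of 3) exceeded the other 9 libraries. This does not decide against a mixture of all these cells. Knockout 1 lacked some transcripts present in every other library, such as Atg14 (0 CPM, at least 21.06 elsewhere), which can lower such scores. Among single markers, Sftpd at 135.5 CPM and Ramp2 at 13.8 exceeded those 9 (at most 94.2 and 7.14), while Napsa at 23.4 and Cldn5 at 4.40 did not. Fibroblasts alone may add to its distance, since 9 of 12 fibroblast genes exceeded the other 9 libraries. Lum and Pdgfra, at 0 and 0.452 CPM, did not, and mesenchymal tumour cells could give the same values. The genotype cannot be told apart from chance here, because 0.182 of all pairs of libraries are both knockouts.

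The p53 and NRF2 lists were higher in every knockout library than in any control. The difference did not rest on knockout 1 and 4 alone. Without both, the list means still differed by 0.219 ± 0.0411 (SE) for p53 and 0.196 ± 0.0659 for NRF2, and camera passed both (adjusted p = 3.23e-06 and 0.0017). This follows largely from the choice of the pattern, as every knockout library lay above every control, so it is no separate support. The NRF2 list is the weaker of the 2, as with all libraries it did not pass at an estimated correlation (adjusted p = 0.358, p53 0.0169) or by fry (0.16, p53 0.00322). Lung epithelial cells are argued against as the whole cause, since with the lung epithelial score as covariate the difference stayed at 0.226 ± 0.0474 (SE) for p53 and 0.247 ± 0.0673 for NRF2. Fibroblast and endothelial scores were not used as covariates, so a part played by those cells stays open. Stress of dissociation, as far as immediate-early genes show it, is argued against, as their score differed by -0.123 ± 0.0939 (SE) against 0.255 for the p53 and 0.267 for the NRF2 list. An effect of Atg12 loss was not tested apart from the group itself and stays open, as do other technical causes that follow the genotype.

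The basal list was higher and the luminal and milk lists lower by camera at its preset correlation, but none passed at an estimated correlation (adjusted p = 0.46 each) or by fry (0.329, 0.38 and 0.329). For the luminal and milk lists the pattern may come from knockout 1 and 4, since without both the list means differed by 0.0708 ± 0.047 (SE) and -0.165 ± 0.221, against -0.226 and -0.939 before, and camera passed neither. For the basal list this cannot be told apart, as the difference was then 0.234 ± 0.155 (SE) while camera still passed (adjusted p = 0.0002). Lung cells also cannot be told apart for it, since with the lung epithelial score as covariate the difference was 0.173 ± 0.187 (SE), under its own error, against 0.437 before, while camera still passed (adjusted p = 0.0168).

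Of 100 splits of the 11 libraries into 6 and 5, only the real one (1) gave as many as 2 genes past the threshold, the highest other giving 0. The others gave 0 whether knockout 1 and 4 fell in the same group or not. Chance is thus argued against for that count, but not excluded, as these splits are only a sample of those possible. The count also fell to 0 without any 1 of the 6 controls, or without knockout 1, 4 or 5. For the 1045 genes at an unadjusted p under 0.05, 8 of 100 splits gave as many, the highest other giving 1565, so chance cannot be excluded for that number. For lists, 20 of 100 splits gave 13 or more, the highest other giving 16 and the median of the others 9, so chance cannot be excluded for the number of lists.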

How the results depend on the processing

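The exact permutation of list means, the fits without knockout 1 and 4 and the lung epithelial covariate were chosen after seeing the data. The 2 genes past the threshold were the same genes with RLE or upper-quartile factors, with no low-count filter and with a stricter one. DESeq2 gave 15 genes, all 15 higher, voom 6 (5 higher, 1 lower), and a minimum log2 fold change of 1 left 1. The macrophage covariate and the lung epithelial covariate each gave 0 genes, 0 of them higher (616 and 646 at an unadjusted p under 0.05). Leaving out 1 library at a time gave 0 to 2 genes, all higher, and leaving out knockout 1 and 4 gave 2 higher and 1 lower. With the replicate number as a block there were 0 genes, 0 higher (719 at an unadjusted p under 0.05). Whether the numbers pair the samples is not settled. Deviations of same-numbered libraries correlated at 0.116, -0.0874, 0.0329, 0.152 and 0.129, not all of them over the 0.1 set for pairing. Libraries 1, 4 and 5 correlated best with the control of their own number, 2 and 3 with control 5. With that block the endothelial list passed (median 0.51, adjusted p = 0.0476). Atg12 passed with voom (log2 -0.69, adjusted p = 0.0403) and without knockout 1 and 4 (-0.68, adjusted p = 0.0462), its log2 being negative throughout. Lists past the threshold fell from 13 to 1 with an estimated correlation, 1 with fry and 2 with exact permutation. The cause of these differences was not tested, beyond fewer libraries in the reduced fits. The fibroblast list reversed with voom (median -0.0194), the luminal list in camera direction without knockout 1 and 4 (-0.0287), and the interferon list with the macrophage covariate (-0.0868), without knockout 1 and 4 (-0.14) and over single libraries left out (-0.0184 to 0.291). The authors' deposited table holds 46 genes past an adjusted p of 0.1 in place of 10. Of 61 named genes other than Atg12, 55 kept their sign in every alternative, and 12 lists kept their camera direction. Hexa, Lck and Ramp2 had negative values with voom (-0.03, -0.20 and -0.46) and without knockout 1 and 4 (-0.12, -0.22 and -0.46), where Bst2 (-0.002) and Mgp (-0.11) did too. Lck was at -0.33 without knockout 1, and Lyz1 at -0.13 with the lung epithelial covariate.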

Other observations

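The tests of the genes around Atg12 and of macrophages and lung epithelial cells were chosen after the result was seen.

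The immediate neighbour of the deleted gene was among the genes that differed most. Cdo1 (ENSMUSG00000033022, chromosome 18, 46713205 to 46728342), which encodes the cysteine dioxygenase that turns cysteine towards taurine, starts 4074 bases from the 3' end of Atg12 as deposited and lies on the same strand in GENCODE M21. There the last exon of Atg12 reaches further towards Cdo1, to 46730144. Cdo1 differed between the groups. It was at 2.15 ± 1.07 CPM in controls (SD, n = 6) and 10.4 ± 4.08 CPM in knockouts (SD, n = 5), a log2 fold change of 2.31 ± 0.39 (SE), with all 5 knockout libraries above the highest control. Its p ranked 3 of the 13078 genes by edgeR (adjusted p = 0.158). It is past the threshold in the authors' deposited table and by DESeq2. Ap3s1, on the other side of Atg12 at a gap of 296 bases, was at -0.13 ± 0.15. A change of the whole region is argued against, since among the other 9 tested genes within 500 kb the highest log2 plus 2 standard errors was 1.29, below the 1.54 that Cdo1 keeps after subtracting 2 standard errors, and their median log2 was -0.01. A local effect of the deletion on the next gene, such as transcripts that read on past Atg12, may be a candidate explanation. The counts per gene hold no test of it, so an effect through autophagy stays open.

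Interferon and antigen presentation genes varied strongly inside both groups. The MHC class I list mean ran from 7.45 to 9.38 log2 CPM in controls and from 8.15 to 9.37 in knockouts. Cd74, the MHC class II chaperone, ran from 47.8 CPM in control 5 to 3687 CPM in knockout 4. It was predicted before the test that a shared interferon state would tie MHC class II genes to the interferon list. Over the 11 libraries the mean of 7 class II genes followed it, with r = 0.956 (permutation p = 1e-05, the smallest 100000 resamples can give) and rho = 0.945 (permutation p = 3e-05). Without control 5 and knockout 2, the libraries farthest from the median, r was 0.949 (permutation p = 0.00023), and within the 6 controls it was 0.965 (permutation p = 0.00132). This was the only relation of its kind computed. It is consistent with differing interferon exposure of the sorted cells. Macrophages also express class II genes but are argued against as the source of this variation. Over the libraries the log2 sum of 16 other macrophage genes, lysozymes left out, rose by 0.0486 ± 0.0799 (SE) per log2 unit of the class II sum, where a shared source would give about 1, and stayed between 6.66 and 27.4 CPM while the class II sum ran from 92.2 to 8010. Lung epithelial cells, some of which make class II genes, are argued against in the same way (20 genes, -0.0322 ± 0.125).

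Another pair of hypotheses was tested and not borne out. Txnip is a known FOXO target, and Pdk4, Angptl4 and Cpt1a, known PPAR targets, had unadjusted p of 0.00106, 0.00107 and 0.00204 (adjusted p = 0.579 for each), so FOXO targets and PPAR and fatty acid oxidation genes, without those already seen, were predicted to be higher. The FOXO set of 20 genes differed by 0.0106 log2 units (exact permutation p = 0.905), and the PPAR set of 20 genes by 0.0118 (exact permutation p = 0.926). In each, 4 of 5 knockout libraries lay above the control median, and 2 standard errors above the difference was 0.164 and 0.243.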
